A study of Homo sapiens with 2 samples.

How the data were processed

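RNA of 2 HEC1A cell lines, 1 overexpressing EMP2 and 1 with EMP2 knocked down, was hybridized to 1 Affymetrix array each. Per the labels' protocols, total RNA was purified with a Qiagen kit, the cells were grown with serum and were otherwise untreated, and the RNA was labelled with biotin through the Affymetrix WT terminal labelling kit, a whole-transcript kit, while the probe sets are those of a 3' expression array, so which priming was used is unclear. The submitters' processing notes name Partek 6.6 and no other tool. The background correction, the normalization and the summarization of probes into probe sets are not given in the sources used here.

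The table deposited by the authors holds 1 value on a log2 scale per probe set and array. The base of 2 was taken from the range, 2.01 to 14.72, and is not stated. The medians over all 54675 probe sets were 6.02 and 6.01, and the sorted values of the arrays differed by at most 0.05, with a median gap of 0.005, so the arrays had been brought to nearly the same distribution before deposit. A real shift common to most genes would have been removed by that step. In 8008 probe sets (14.6%) both arrays had the identical value. Detection calls and probe-level intensities were not used here. No depth applies to arrays.

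Probe sets were named from the platform's annotation table, in which 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none. Those with several or none entered no gene-level comparison. Of the single-symbol probe sets, 41043 had an Entrez identifier found in the RefSeq gene table of GRCh38.p14, and 0 of their symbols needed an update. Of 19775 genes, 10523 had more than 1 probe set, and the probe set with the highest mean of both arrays stood for the gene. A gene passed the filter if the higher of its 2 values reached 6.40, the median over both arrays of all single-symbol probe sets. This kept 12061 genes (61.0%). Values were used as deposited, with no further scaling and no pseudocount.

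With 1 array per group there is no test across genes. Genes were counted by size, at 2-fold. Members of a list were counted at 1.5-fold, a threshold set after the design was fixed. The genes named were EMP2, the 15 genes past the filter with the largest positive and the 15 with the largest negative difference, leaving out LOC names, small RNAs, pseudogenes and uncharacterised open reading frames, and in each list described the members with the largest absolute differences, up to 4. A few further list members, such as CD44, CCN2, LATS2, EGFR, CAV1 and the members that differed the other way from their list, and the gene families of the closing section, were chosen after their values were seen. As a background level, 27 probe sets for Bacillus subtilis control transcripts were used, with a median of 3.41 and a highest value of 5.85. Where the lower of a gene's values did not exceed 5.85, the fold was computed against 5.85 and is given as a lower bound. This background level was chosen after seeing the data.

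For each of 31 gene lists the median difference of the members past the filter was set against 10000 random lists of the same size, drawn from the genes past the filter in 20 bins of mean expression. A list was said to stand apart when it lay outside the central 95% of these. The percentile describes these arrays and does not test the conditions. Lists with fewer than 5 members past the filter have values of their members only. The lists cover the aldehyde dehydrogenase family, stem cell markers, the PMP22/EMP family, epithelial junctions and keratins, mesenchymal genes, integrins and focal adhesion, hypoxia targets, angiogenic factors, caveolae and flotillins, cell cycle, interferon-stimulated genes, MHC class I presentation, cholesterol synthesis, the unfolded protein and integrated stress response, NRF2 targets, steroid hormone response, the retinoid pathway, TGF-beta and BMP targets, YAP/TEAD targets, NF-kB and inflammatory genes, p53 targets, ERBB and MAPK output, Wnt targets, the Notch pathway, matrix proteases, immediate early genes, ribosomal protein genes, and endometrial epithelium, endothelial, leukocyte and fibroblast markers. Members without a single-symbol probe set in the annotation used are not analysed here. The lists, the filter, the 2-fold threshold, the random-list range and the alternatives were fixed before the data were examined, apart from those named as later choices.

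The procedure was tested on simulated data. Among 11927 simulated genes, with a noise SD of 0.1 log2 units chosen for the simulation, 100 of 100 raised and 100 of 100 lowered by 1.5 log2 units passed the 2-fold threshold and 0 unchanged genes did. Of 200 unchanged lists of 15 genes 5.50% stood apart, and of 100 lists with each member shifted by 0.3 log2 units 100% did. This checks the code, and it does not show how many of the measured differences are noise, which 1 array per group cannot tell. Other settings fixed at the start were median centring, quantile normalization, removal of a loess trend (span 0.3), averaging of probe sets, no filter, a filter at the 75th percentile, thresholds of 1.5-fold and 3-fold, list means, unmatched random lists, and lists without their most different member. A pseudocount did not apply to values on a log scale. Alternatives added after seeing the data raised all values to the bacterial control level, or left out stretches of neighbouring genes that were jointly higher. Those stretches were found after seeing the data, from medians over 30 neighbouring genes above all of 100 shuffles of gene order. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.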

Results

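Gene expression was measured in HEC1A, an established human endometrial adenocarcinoma cell line, in 2 stable states of EMP2 expression. EMP2 is epithelial membrane protein 2, a small tetraspan protein of the PMP22 family. One array held RNA of cells that overexpress EMP2 and one held RNA of cells that carry a short hairpin RNA vector against it, so there was 1 array per group and no replicate. The comparison asks how expression differs between HEC1A cells labelled EMP2 overexpression and EMP2 knockdown. Both lines were engineered and no unmodified HEC1A array was analysed here, so a difference cannot be assigned to the overexpression or to the knockdown. The number of arrays limits the precision. No difference below has a replicate check, and none carries a p-value. Each difference is the log2 value in overexpression minus that in knockdown. The table held 54675 probe sets, of which 41097 had 1 gene symbol and stood for 19775 genes. A total of 12061 genes passed the brightness filter. Across all probe sets the arrays correlated at r = 0.993 (Pearson, across probe sets, which are not independent replicates). The 18 bacterial and phage hybridization controls differed by at most 0.10.

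EMP2 itself was higher in the overexpressing cells. Its brightest probe set read 12.25 in overexpression and 9.51 in knockdown, a difference of 2.74 or 6.68-fold, which placed EMP2 at rank 13 from the top among the 12061 genes. The other 3 EMP2 probe sets did not show this difference. They read 10.44 against 10.05, 9.67 against 9.43 and 5.93 against 5.93, which are differences of 0.39, 0.23 and 0.00. With the 4 probe sets averaged, the difference was 0.84. The direction of the brightest probe set followed the labels, but where the probe sets lie within the transcript was not known here. Of the relatives of EMP2, PERP was lower by 2.53-fold in overexpression (11.41 against 12.74), and EMP3 by 2.02-fold (9.87 against 10.88). EMP1 differed by -0.19 and TMEM47 by 0.42.

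**Figure D1:**
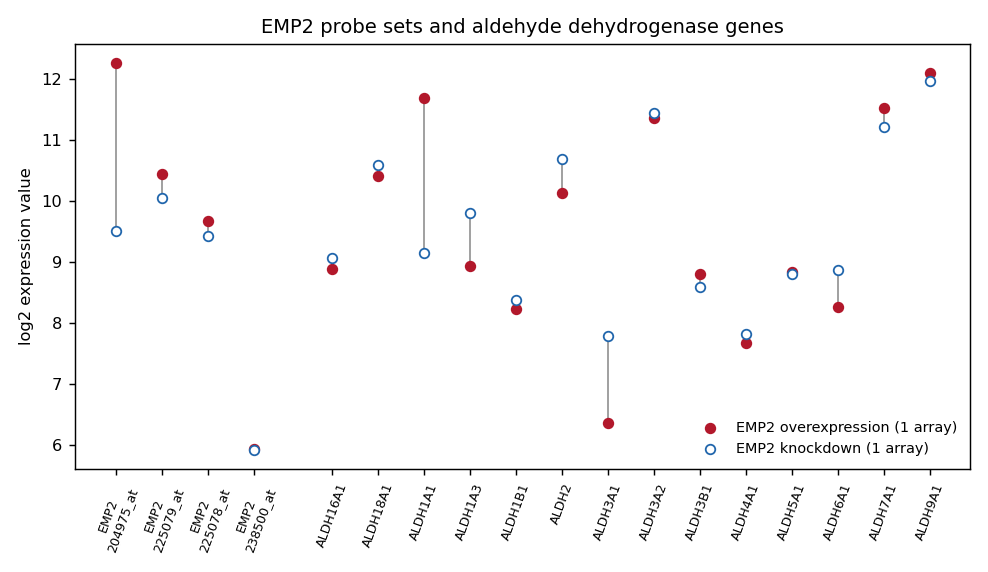
Log2 expression values (vertical axis) of the 4 EMP2 probe sets and of the 14 aldehyde dehydrogenase genes that passed the filter, with a filled point for the overexpression array, an open point for the knockdown array and a line joining them. The brightest EMP2 probe set and ALDH1A1 differ by 2.74 and 2.54 in the same direction, while most other aldehyde dehydrogenases lie close together.

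In all, 199 genes were at least 2-fold higher in overexpression and 185 were at least 2-fold lower, which together were 3.18% of the genes past the filter. CST6, a secreted inhibitor of cysteine proteases, was 20.2-fold higher (11.72 against 7.38). CAVIN1, a coat protein of caveolae, was 11.4-fold higher (10.25 against 6.74). EFNB2, the ligand ephrin B2, was 7.66-fold higher, SCIN, an actin-severing protein, 7.17-fold, RIPOR3 6.72-fold, and F2R, the thrombin receptor, 6.53-fold. The knockdown value of SCIN, 5.95, was close to the brightest bacterial control. For 8 of the 15 genes with the largest positive differences, the knockdown value was not above the brightest bacterial control (5.85), so only a lower bound can be given. SCD5, a stearoyl-CoA desaturase, was at least 11.1-fold higher, the neural adhesion protein CNTN6 at least 8.20-fold, the matrix cross-linking enzyme LOXL2 at least 8.14-fold, the adhesion molecule L1CAM at least 7.86-fold and CCSER1 at least 7.10-fold. TCHH was at least 6.17-fold higher, the noncoding RNA FAM230C at least 3.35-fold and DOCK2, an exchange factor for Rac, at least 1.96-fold. EMP2 was the remaining gene of the 15.

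CA12, a membrane carbonic anhydrase, was 9.41-fold lower (8.30 against 11.54), with 5 of its 6 probe sets past the filter at least 2-fold lower. CD163L1, a scavenger receptor, was 17.3-fold lower. The matrix glycoprotein tenascin C (TNC) was lower by 3.59 log2 units (7.81 against 11.40), the sialic acid-binding receptor SIGLEC15 9.55-fold and the fibrinogen beta chain (FGB) 9.48-fold. For the other 10 of the 15 genes with the largest negative differences, the overexpression value was not above the bacterial controls. The antisense RNA TMEM132D-AS1 was at least 15.6-fold lower, the heparan sulfate sulfotransferase HS3ST1 at least 12.5-fold, and the chromatin organiser SATB1 at least 9.20-fold. EHF, an ETS factor of epithelial cells, was at least 8.36-fold lower, and SGCE, epsilon-sarcoglycan, at least 8.13-fold. SCEL, a precursor of the cornified envelope, was at least 5.88-fold lower, FAM241A at least 5.06-fold, the chemokine CXCL8 at least 4.93-fold, the histamine methyltransferase HNMT at least 4.36-fold and the potassium channel subunit KCNV1 at least 2.36-fold. Other probe sets of the same gene often did not share the difference. Of the genes at least 2-fold higher, 66 had another probe set past the filter, and in 34 of these another was at least 2-fold higher too. Of the lower genes 55 had one, and in 36 another was at least 2-fold lower. Only 1 of 2 probe sets past the filter was 2-fold apart for L1CAM, F2R, HS3ST1 and CXCL8. The counts depended on how probe sets of one gene were combined. With a gene's probe sets averaged, 122 genes were at least 2-fold higher and 106 at least 2-fold lower. Of the 29 named genes besides EMP2, 19 moved by more than 1.5-fold, and SCD5 (0.94), LOXL2 (0.75) and HNMT (-0.73) were then below 2-fold. The average takes in probe sets below the filter too. Only 1 of 4 probe sets of SCD5, 1 of 4 of LOXL2 and 1 of 6 of HNMT passed it.

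**Figure D2:**
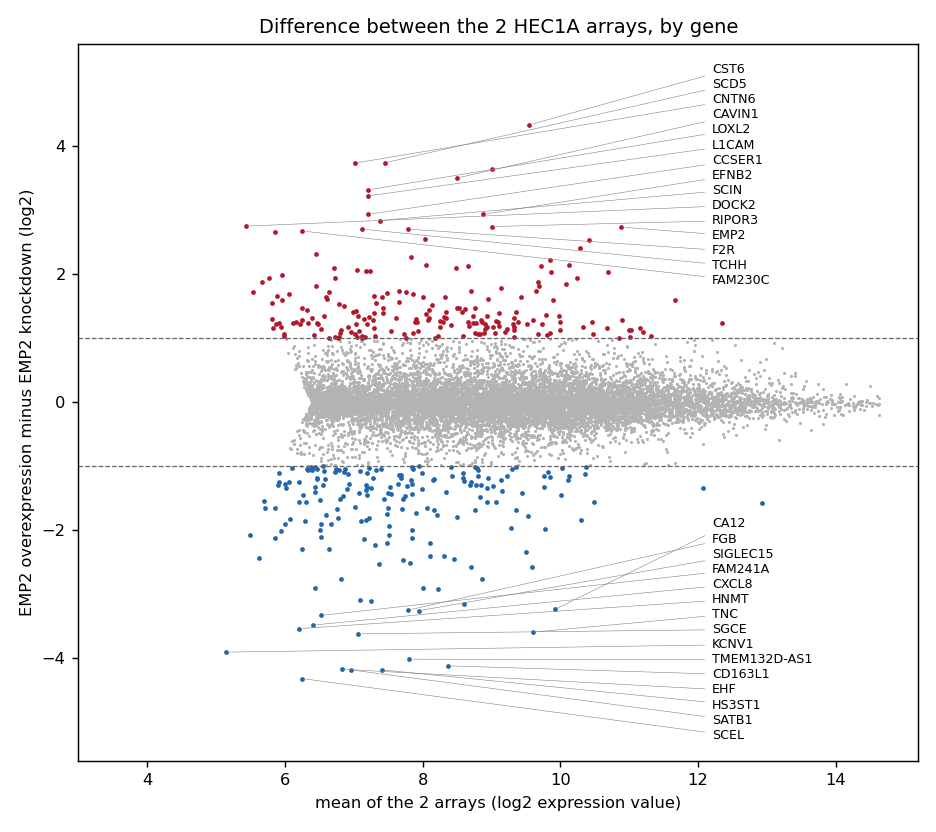
Difference between the arrays in log2 units (vertical axis, overexpression minus knockdown) against the mean of both arrays (horizontal axis, log2) for the 12061 genes past the filter, 1 point per gene. Red points are the 199 genes at least 2-fold higher and blue points the 185 at least 2-fold lower, dashed lines mark 2-fold, and the 15 named genes at either end are labelled.

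The fixed gene lists were compared with random lists matched on expression. Of 31 lists, 27 had at least 5 members past the filter. The medians of 9 lists lay above the central 95% of random lists and those of 4 lay below it, where 1.35 lists outside would be expected from unrelated genes. Some lists share members, so they are not independent of each other. Among all genes past the filter, 4.97% were at least 1.5-fold higher and 4.15% at least 1.5-fold lower. The positions of 5 lists held under each alternative run, namely cholesterol synthesis, interferon-stimulated genes, YAP/TEAD targets, NF-kB and inflammatory genes, and ERBB and MAPK output. The other 8 each returned to the random range under at least 1 alternative.

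**Figure D3:**
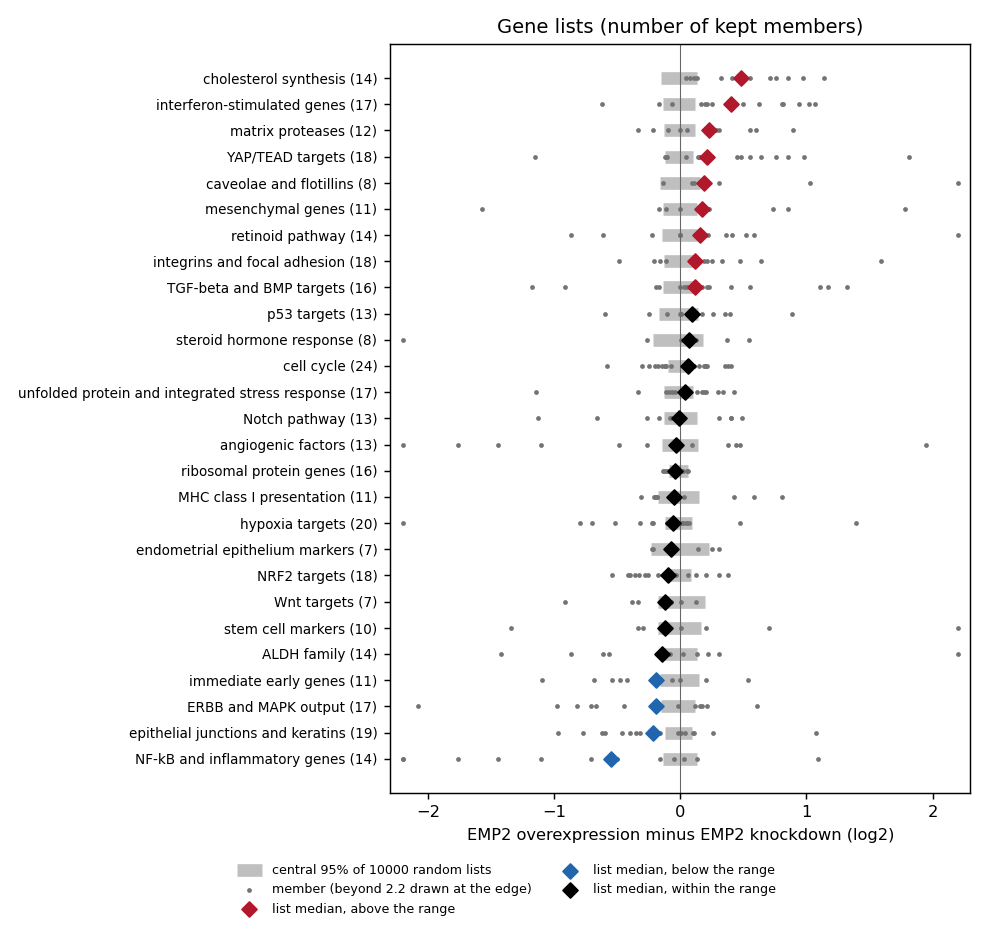
Medians (diamonds) and members (small points) of the 27 gene lists, as log2 difference of overexpression minus knockdown (horizontal axis), with grey bars for the central 95% of 10000 random lists of the same size and expression, and members beyond the axis range at its edge. Cholesterol synthesis (0.48) and interferon-stimulated genes (0.41) have the highest medians, and NF-kB and inflammatory genes (-0.55) the lowest.

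ALDH1A1, a retinaldehyde dehydrogenase used as a marker of stem-like tumour cells, was 5.80-fold higher in overexpression (11.68 against 9.14, on its only probe set). The rest of the aldehyde dehydrogenase family did not share this difference. Of 14 family members past the filter, 1 was at least 1.5-fold higher and 3 were at least 1.5-fold lower. The lower ones were ALDH3A1 (2.68-fold), ALDH1A3 (1.83-fold) and ALDH6A1 (1.53-fold). The family's median was -0.15, at the 3.65th percentile of random lists. It was below the random range with probe sets averaged, with no filter and without expression matching, at the 1.06th, 1.02nd and 2.32nd percentiles. Of 10 stem cell markers, 2 were at least 1.5-fold higher, ALDH1A1 and THY1 (0.70), of which THY1 lies in a stretch of neighbouring genes that were jointly higher. The chemokine receptor CXCR4 was at least 1.78-fold lower. CD44 differed by 0.20, MYC by -0.34 and MSI2 by -0.30. The stem cell list's median was -0.12 and its mean 0.11, and the median lay within the random range, at the 8.83rd percentile.

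Genes of the retinoid pathway had a median of 0.15, at the 98.4th percentile. ALDH1A1 led them, and of the other 13 none was 1.5-fold higher, while ALDH1A3 and RDH10 (-0.61) were lower. PLAAT4, at 0.58, and TGM2, at 0.52, had the next largest positive values. Without ALDH1A1 the list lay at the 97.3rd percentile, within the random range, and without a brightness filter at the 85.3rd.

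Inflammatory genes were lower in the overexpressing cells. Of 14 NF-kB targets and cytokines, 7 were at least 1.5-fold lower and 1 at least 1.5-fold higher, with a median of -0.55 that lay below all 10000 random lists. The neutrophil chemokine CXCL1 was 3.39-fold lower and CCL20, a chemokine for lymphocytes and dendritic cells, 4.60-fold. CXCL8 was at least 4.93-fold and CXCL2 at least 2.19-fold lower. ICAM1, an adhesion molecule, was 2.13-fold higher. Of 13 angiogenic factors 4 were at least 1.5-fold lower, namely CXCL1, CXCL2, CXCL3 and CXCL8. THBS1, an inhibitor of vessel growth, was 3.86-fold higher on its brightest probe set, and 4 of its 4 probe sets past the filter were at least 2-fold higher. The angiogenic list's median of -0.04 was within the random range. Its mean of -0.40 lay below it, at the 0.83rd percentile. That mean takes the values as deposited, with CXCL8 at -3.48. The overexpression values of CXCL8, CXCL2 and CXCL3 were not above the bacterial controls, and no mean with bounded values was computed. With a filter at the 75th percentile the angiogenic median was 0.24, within the range at the 97.0th percentile.

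Genes of ERBB signalling and its feedback were also lower, with a median of -0.19 at the 0.60th percentile. Of 17 members, 5 were at least 1.5-fold lower and 1 was higher. The ERK phosphatase DUSP4 was 4.22-fold lower, with 3 of 3 probe sets at least 2-fold lower, the EGFR ligand EREG 1.97-fold, ERBB3 1.77-fold and DUSP6 1.63-fold. EGFR differed by -0.67. PHLDA1 was 1.53-fold higher. Immediate early genes had a median of -0.19, at the 1.30th percentile, with EGR1 2.14-fold lower, JUN 1.61-fold lower and 9 of 11 members under 1.5-fold. By the mean of its members this list lay within the random range, at the 3.36th percentile.

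Epithelial junction and keratin genes had a median of -0.21, at the 0.02nd percentile, and 4 of 19 were at least 1.5-fold lower. These were the keratins KRT19 (1.96-fold) and KRT8 (1.70-fold), the desmosomal protein DSP (1.54-fold) and the tight junction protein TJP3 (1.52-fold). CDH1, which encodes E-cadherin, differed the other way and was 2.11-fold higher. With probe sets averaged the list lay at the 4.71st percentile, within the random range. The mesenchymal list had a median of 0.17, at the 98.95th percentile. CDH2, which encodes N-cadherin, was 3.44-fold higher on 1 of its 2 probe sets and under 2-fold on the other, the receptor AXL 1.81-fold and fibronectin (FN1) 1.67-fold, while S100A4 was 2.98-fold lower and the other 7 of 11 were under 1.5-fold. By the mean of its members the mesenchymal list lay at the 95.3rd percentile and without a brightness filter at the 95.9th, both within the random range.

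Cholesterol synthesis genes were jointly higher in overexpression. All 14 members measured were above 0, 5 of them by at least 1.5-fold and none lower, with a median of 0.48 above all 10000 random lists. The list had 20 members when it was fixed. INSIG1, which retains SREBP in the endoplasmic reticulum, was higher by 1.14 log2 units, squalene epoxidase (SQLE) 1.96-fold, the isomerase IDI1 1.81-fold and HMGCS1 1.69-fold. Interferon-stimulated genes had a median of 0.41, also above all random lists. Of 17 members, 6 were at least 1.5-fold higher, among them IFI6 (2.09-fold), IFI44 (2.03-fold), RSAD2 (1.92-fold) and MX1 (1.75-fold). IFIH1, a sensor of double-stranded RNA, was 1.54-fold lower. RSAD2 and MX1, and LSS and SC5D of the cholesterol list, lie in stretches of neighbouring genes that were jointly higher. Without the genes of these stretches the medians were 0.40 for the interferon list and 0.44 for the cholesterol list, both still above all random lists.

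Targets of YAP and TEAD had a median of 0.21, at the 99.95th percentile. Of 18, 5 were at least 1.5-fold higher and 1 was lower. ANKRD1 was at least 2.84-fold higher, NT5E 1.98-fold, AXL 1.81-fold and LATS2 1.69-fold, while tissue factor (F3) was 2.22-fold lower. CCN2 and CCN1, also targets, differed by 0.55 and -0.12. For LATS2, 2 of 3 probe sets past the filter were higher. Integrin and focal adhesion genes had a median of 0.12, at the 98.2nd percentile. The integrin subunit ITGB5 was 3.02-fold higher and ITGB3 1.56-fold, and the other 16 of 18 were under 1.5-fold. For ITGB3, only 3 of 6 probe sets past the filter were higher. For ITGB8, 1 of 2 was at least 2-fold higher, though the brightest differed by 0.12. Without ITGB5 the integrin list lay at the 96.7th percentile and with probe sets averaged at the 97.2nd, both within the random range. Of 8 caveolae and flotillin genes, CAVIN1 and CAVIN2 (2.04-fold) were higher and CAV1 differed by 0.21. Their median was 0.19, at the 98.7th percentile, and without CAVIN1 they lay at the 97.4th, within the random range. Matrix proteases and their inhibitors had a median of 0.23, at the 99.8th percentile, with TIMP2 1.85-fold and ADAM17 1.52-fold higher and 10 of 12 under 1.5-fold. ADAM17 lies in one of the jointly higher stretches. By the mean of its members the protease list lay at the 96.4th percentile. TGF-beta and BMP genes had a median of 0.11, at the 97.8th percentile. TGFB1 (1.32 log2 units), ID3 (1.17) and LTBP2 (1.11) were higher and TGFBI (-1.18) and BAMBI (-0.91) were lower. This list lay within the random range with no filter (89.7th percentile), by the mean of its members (96.6th), without expression matching (97.2nd), without TGFB1 (88.7th) and without the jointly higher stretches (90.8th).

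The other lists lay within the random range. Of 24 cell cycle genes, none differed by 1.5-fold, and their median was 0.06, which lay above the random range without the most different member (98.3rd percentile). Of 20 hypoxia targets, 1 was at least 1.5-fold higher (ADM, 2.62-fold) and 3 were lower, led by CA12. Their median was -0.05, but their mean of -0.21 lay below the random range, at the 0.85th percentile. That mean includes CA12 at -3.23, and a mean without CA12 was not computed. None of 18 NRF2 targets differed by 1.5-fold, with a median of -0.10 at the 3.41st percentile. This list lay below the random range with no filter (0.13th percentile) and with a filter at the 75th percentile (2.27th). JAG1, a Notch ligand, was 2.18-fold lower and NOTCH1 1.58-fold lower in a Notch list with a median of -0.01. Only 1 of 2 NOTCH1 probe sets past the filter was lower. ASNS, an ATF4 target, was 2.21-fold lower in a stress response list with a median of 0.03. Of p53 targets, GDF15 was 1.85-fold higher and ZMAT3 1.51-fold lower, with a list median of 0.09. The Wnt list's median was -0.12, with BAMBI the only member at least 1.5-fold lower, and it lay below the random range with probe sets averaged (0.32nd percentile). MHC class I genes had a median of -0.05 and a mean of 0.06, and PSMB9, an immunoproteasome subunit, was 1.74-fold higher. In the steroid hormone list, CA12 was lower and the other 7 members were under 1.5-fold, with a median of 0.07 and a mean of -0.29. Of 15 endometrial epithelium markers measured, 7 passed the filter, and none of these differed by 1.5-fold on its brightest probe set. For FOLR1, 1 of 2 probe sets past the filter was at least 2-fold lower. PAX8, a transcription factor of Mullerian epithelium, read 11.26 and 11.33.

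Markers of other cell types were dim on both arrays. Of 10 endothelial markers 7, of 10 leukocyte markers 5 and of 10 fibroblast markers 5 were not above the bacterial controls, and the median differences of these lists over all measured members were -0.04, 0.00 and 0.00. The brightest of these markers was COL1A1, at 8.51 and 8.48. The other fibroblast marker past the filter was THY1, which differed by 0.70. Ribosomal protein genes, with 16 members, had a median of -0.05 and none differed by 1.5-fold. The 3 probe sets for 18S ribosomal RNA were lower in overexpression by 0.47 to 1.09 log2 units. The 3' minus 5' difference, a measure of RNA integrity where labelling starts from the 3' end, was -0.04 and -0.02 for GAPDH and 1.07 and 1.02 for ACTB, in overexpression and knockdown.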

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

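All tests in this part were chosen after the results they bear on were seen, except those on the unused probe sets of shifted stretches and on the interferon genes outside them, and the test of ordinary probe set disagreement was widened, with its interval added, after a first version rested on 2 genes, while those of signal strength and RNA degradation were revised after their first results.

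Some signals lay outside the gene-level comparison. A probe set without a gene name in the annotation used differed by 7.54 as deposited, reading 9.80 in overexpression and 2.26 in knockdown. Its knockdown value lies below the brightest bacterial control, against which the difference is at least 3.95. Of 4 RAP1A probe sets, 2 differed by 7.63 as deposited (at least 5.45 against the bacterial controls) and 5.24, while the brightest, which stood for the gene, and the remaining one differed by -0.03 and -0.07. The 5' probe set for 18S ribosomal RNA, an array control, differed by -1.09. In all, 37 unnamed probe sets past the filter were at least 2-fold higher and 19 at least 2-fold lower, and 8 and 10 of those with several symbols were.

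EMP2's brightest probe set differed by 2.74 and its other 3 by at most 0.39. The values argue against dimness, since 2 of those 3 read at least 2 log2 units above the brightest bacterial control on both arrays. Ordinary disagreement between probe sets stays open: among 24 other genes at least 4-fold apart that had a further probe set past the filter, 4 (16.7%, exact 95% interval 4.74 to 37.4) had none that differed by 0.5 the same way. A candidate explanation is that the overexpressed sequence lacks the part read by the other probe sets, whose largest difference was 0.39, and this cannot be told apart without probe positions. Under that explanation, those probe sets would read the cells' own EMP2. They were then at most 1.31-fold lower in the knockdown cells than in the overexpressing cells, so they show no large fall in EMP2 RNA. Without an unmodified array the depth of the knockdown was not measured.

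Neighbouring genes shifted together, since with 12038 genes in RefSeq order (GRCh38.p14) the highest median over 30 neighbours was 0.52, against at most 0.23 in 100 shuffles of gene order, of which 0 reached 0.52. Windows above the shuffles formed 5 stretches with 559 genes and a median of 0.31. Shuffles within 20 bins of mean expression keep a bias with signal strength. Their highest window was 0.28, and none of 100 reached 0.52. The weakest stretch, on chromosome 9, peaked at 0.26, which 1 of these shuffles reached, so it would not exceed all shuffles of this kind. The other stretches peaked at 0.31 to 0.52, which argues against such a bias as their source. Extra copies of these stretches in the overexpressing cells, or fewer in the knockdown cells, cannot be told apart from each other or from regional regulation. Of 464 probe sets of the same genes not used to find them, 78.7% were higher, with a median of 0.29. For other genes 46.4% were higher, with a median of 0, where equal values count as not higher. Each of these explanations would give this. No DNA was measured, and a difference that arose between the lines before or during their selection is confounded with EMP2 state.

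Interferon-stimulated genes were higher in overexpression, with a list median of 0.41. Members inside the shifted stretches do not account for it alone, because the other 15 had a median of 0.40 against a random upper bound of 0.13. Unequal RNA degradation cannot be told apart: the 3' minus 5' differences of GAPDH and ACTB differed between arrays by at most 0.0405, but they read integrity poorly if the whole-transcript labelling named in the labels was used, and the 18S controls differed by up to 1.09. An effect of EMP2, a difference in culture, and a dose of the interferon receptor genes that differs between the lines stay open with 1 array per group. Those receptor genes are listed under the other observations.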

How the results depend on the processing

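The settings that raised values to the bacterial control level or left out the shifted stretches were chosen after seeing the data, and the others were planned. Of 475 recomputed values, 410 kept their side of the threshold or moved by less than 1.5-fold, and no called list or named gene reversed. Of the list values, 6 took the opposite sign, all within the random range before and after, among them angiogenic factors with the stricter filter (97.0th percentile) and, by list means, steroid hormone response (3.19th) and stem cell markers (83.4th). Median centring, quantile normalization and loess changed no list's call, gave 198 to 205 genes at least 2-fold higher and 181 to 185 lower, and moved the median of all genes past the filter by at most 0.01. The deposited arrays already had nearly the same distribution, so median centring and quantile normalization could change little. Their values, which count among the 410, do not test the normalization made before deposit. With probe sets averaged, EMP2's difference was 0.84, and 122 genes were at least 2-fold higher and 106 lower. A filter at the 75th percentile gave 116 and 86 with fewer genes counted, a 1.5-fold threshold 600 and 500, and a 3-fold threshold 65 and 76. Percentiles of lists moved as follows, and the cause was not tested. With probe sets averaged, the aldehyde dehydrogenases (1.06) and Wnt targets (0.32) came to stand apart, and epithelial junctions (4.71) and integrins (97.2) no longer did. With no filter, aldehyde dehydrogenases (1.02) and NRF2 targets (0.13) came to stand apart and mesenchymal genes (95.9), the retinoid pathway (85.3) and TGF-beta (89.7) no longer did. With the stricter filter, NRF2 targets (2.27) came to, and caveolae (95.2) and the retinoid pathway (92.1) ceased to. By list means, hypoxia targets (0.85) and angiogenic factors (0.83) came to, and mesenchymal genes (95.3), TGF-beta (96.6), matrix proteases (96.4) and immediate early genes (3.36) ceased to. The hypoxia mean includes CA12 (-3.23) and the angiogenic mean CXCL8 (-3.48). Without expression matching, aldehyde dehydrogenases (2.32) came to and TGF-beta (97.2) ceased to. Without the most different member, cell cycle (98.3) came to, and integrins (96.7), caveolae (97.4), the retinoid pathway (97.3) and TGF-beta (88.7) ceased to. Without the genes of the shifted stretches, TGF-beta (90.8) ceased to, and 174 genes were at least 2-fold higher and 181 lower. With all values raised to the bacterial control level, the counts were 183 and 172. Of 29 named genes besides EMP2, 19 moved by over 1.5-fold with all probe sets averaged, those below the filter included, and 3 of the 29 were then below 2-fold. No paired analysis was possible because each group has 1 array and replicate numbers only name samples, and for the same reason no array could be left out. The planned pseudocount did not apply to log values. Signal near background limits the folds of the dimmest genes to lower bounds.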

Other observations

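The groups in this part were chosen after the data were seen. Metallothioneins, small zinc- and copper-binding proteins, were jointly higher in the overexpressing cells. Of 9 MT genes past the filter, 7 were at least 1.5-fold higher, with a median of 0.93 above all 10000 matched random lists. MT1X differed by 1.23, MT2A by 0.94 and MT1E by 0.93, while MT3 differed by 0.06 and MT4 by -0.08. These genes are near-identical copies, so probe sets can share signal and the members are not separate measurements. Among 305 symbol stems with at least 6 genes past the filter, 30 lay outside the central 95% of random lists, against 15.25 expected by chance, and MT and ITGB were the 2 above all of them. The ITGB stem had 12 genes and a median of 0.37, and it mixes integrin subunits such as ITGB5 (1.59) and ITGB1 (0.21) with other genes of like name, such as ITGB2-AS1 (1.25) and ITGB1BP1 (0.58). Of its genes 3 lie in the jointly higher stretches. The ANXA stem (median 0.22, 99.97th percentile) and the CDKN stem (median 0.34, 99.9th percentile, with CDKN1C at 0.91) were also higher. Both mix in other genes of like name, such as ANXA2R-AS1 (1.13) and CDKN2AIP (0.41). The ANXA stem also holds ANXA2 pseudogenes such as ANXA2P1 (0.44). Of its 16 genes 12 were above 0, and ANXA13 was at -0.78. Aldo-keto reductases were lower in 6 of 6 genes, with a median of -0.34 at the 0.05th percentile, none of them by 1.5-fold, with AKR1B10 at -0.54 and AKR1C2 at -0.41. AKR1C1, AKR1C2 and AKR1C3 are close copies too. Of 8 SMAD genes none differed by 1.5-fold. SMAD1, SMAD2, SMAD3, SMAD4 and SMAD5 differed by -0.30 to -0.34, and SMAD6, SMAD7 and SMAD9 by 0.40, 0.17 and 0.07. KLF genes had a median of -0.30, at the 0.10th percentile, with KLF12 at -1.81 and KLF11 at 0.81.

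The 5 stretches of jointly higher genes lay on chromosomes 2, 9, 11 and 21. On chromosome 21 the stretch from C21orf91 to PRMT2 held 120 genes, of which 102 were above 0, with a median of 0.36 or 1.28-fold. That is most of the chromosome's 128 genes past the filter, of which 107 were above 0, with a median of 0.35. The next highest chromosome median was 0.05, on chromosome 15. On chromosome 2 the stretch from FAM110C to NFU1 held 243 genes with a median of 0.34. On chromosome 11 those from SRSF8 to APOA5 (61 genes) and from SIK3 to B3GAT1-DT (95 genes) had medians of 0.21 and 0.31. On chromosome 9 the stretch from NOL6 to GNE (40 genes) had a median of 0.25. The interferon receptor genes IFNAR1, IFNAR2, IFNGR2 and IL10RB, which lie together on chromosome 21, differed by 0.72, 0.57, 0.78 and 0.38. The lowest window median was -0.27, against -0.25 for the lowest in the shuffles. In all, 4 windows lay below the lowest of the shuffles. Stretches were formed from higher windows only, so the genes of these lower windows were not located or left out in any setting.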
